A study of Mus musculus with 6 samples.

How the data were processed

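RNA was taken from retinas of 6 mouse embryos of 1 litter at embryonic day 16.5, 3 labelled Foxp1 cKO and 3 labelled control, with both eyes of an animal combined. Per the labels' protocols, all samples had intact RNA by the electrophoresis score used, ribosomal RNA was depleted, a directional kit was used and the libraries were sequenced as read pairs. Per the submitters' processing notes, the tools were cutadapt 2.8, STAR 2.7.6a, featureCounts 1.5.1 and DESeq2 1.32.0, with the mm10 build. Their settings, including whether counting used the strand, are not given in the sources used here, so counts of overlapping and antisense genes are uncertain.

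The authors deposited whole-number counts of reads per gene for each library, not normalized, for 55487 genes, per the file headers. The authors' deposited table of the comparison of cKO with control holds, per the file headers, the mean normalized count of each gene over all libraries (a signal value of the authors), the log2 fold change with its standard error, a test statistic (a score of the authors), a p-value and an adjusted p-value. Adjusted p-values are missing for 13487 genes of it. The lowest mean normalized count with an adjusted p-value is 658.5 and the highest without one is 658.1. What is printed from it was copied without change. The columns of the count table were matched to samples by the sample descriptions in the labels. Gene names came from the authors' deposited table where it lists the Ensembl identifier, and otherwise from the GENCODE M21 annotation of the same build. Positions, types and summed exon lengths came from that annotation, by Ensembl identifier, which held 55227 of the genes.

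Depth was 23707761 to 25714620 counts per library, and between 24522 and 25118 genes had a count. Genes were kept by edgeR's filterByExpr on the labelled groups, which left 17275. The groups were compared as labelled, and every fold change from the counts is libraries labelled cKO over libraries labelled control. The main test was edgeR 4.0.16 (R 4.3.3) with TMM normalization, a design with genotype alone, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values use TMM-scaled library sizes, with n = 3 per group. The replicates are separate animals per the labels. Pairs of libraries within a group differed by a chi-square per degree of freedom of 7.39 to 12.46 over genes with at least 50 counts in the pair, so none was a duplicate.

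The 31 gene lists, covering retinal progenitor states, retinal cell classes, cell cycle, pathways and other tissues near the eye, were fixed before the data were examined, as were the tests and most alternatives. Each list was tested with camera (limma 3.58.1) on the edgeR object with a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists. Members past the threshold are given over all genes and adjusted over the list alone. The rule for named genes took Foxp1, Foxp2, Foxp4 and Jarid2. It added the 10 protein-coding genes higher and the 10 lower with the largest fold changes past the threshold, with a mean of at least 1 CPM in the higher group and no overlap between groups. From each list it took up to 4 called members per direction, or else the members with the highest CPM, and 5 sex-linked genes served as a check. Other list members named as past the threshold over the list alone, Gm28528, Six3os1, the genes of the interaction test, and ribosomal protein and respiratory chain genes were chosen after their values were seen. The values of some single list members are not reported here.

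The scripts were tested on simulated counts for the comparison of 3 libraries labelled cKO with 3 labelled control, over 17021 tested genes with 50 changed at each of 4 fold sizes. Recovered were 30% of genes changed 1.25-fold, 72% at 1.5-fold, 94% at 2-fold and 98% at 4-fold. Of the calls, 8.1% were false (13 of 160). The simulated counts were drawn for each gene on its own, with no correlation between genes and no length trend. These shares need not hold for the real libraries.

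The alternatives were other normalizations (RLE and upper quartile), other filters on low counts, no robust estimation, DESeq2 1.42.0, limma-voom, labelled sex as a covariate, the replicate number as a replicate block, leaving out chromosomes X and Y, and leaving out each library. Chosen after seeing the data were a sex covariate with the labelled sexes exchanged between groups number for number, with edgeR and DESeq2, removal of the exon length trend of each library by offsets (a lowess curve of span 0.3), and leaving out the 2 libraries whose sex-linked genes go against the label. The labels give all animals as 1 litter and name no batch. The genotype by labelled sex interaction was fitted in edgeR over all 6 libraries.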

Results

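Bulk RNA sequencing was carried out on mouse retinas at embryonic day 16.5, in 3 libraries labelled Foxp1 cKO and 3 labelled control. Per the labels, the cKO animals carried a Cre driven by Six3 sequence, which is active in the developing retina, together with loxP-flanked Foxp1 alleles. The controls were littermates with the loxP-flanked alleles and no Cre. Each library is a separate animal with left and right retinas combined, and all animals came from 1 litter. The labelled sexes were female, female and male for control 1 to 3, and female, male and male for cKO 1 to 3. Total counts per library ranged from 23707761 to 25714620 over 55487 counted genes, of which 17275 passed the filter on low counts. The biological coefficient of variation was 8.4%. The series asks what loss of Foxp1, a forkhead transcription factor, does to gene expression in the embryonic retina.

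Foxp1, the targeted gene, was higher in the libraries labelled Foxp1 cKO than in those labelled control. The gene (ENSMUSG00000030067, chromosome 6, 98925338 to 99522721, minus strand, mm10) had 1850, 1816 and 1742 counts in the libraries labelled cKO 1, 2 and 3, against 1213, 1019 and 1096 in the libraries labelled control 1, 2 and 3. The levels were 72.2 ± 3.36 CPM (SD, n = 3) and 46.0 ± 4.85 CPM (SD, n = 3), a log2 fold change of 0.65 with a standard error of 0.07 and an edgeR adjusted p of 4.63e-05. This direction goes against the labels for a conditional knockout. The exons flanked by loxP sites are not given in the sources used here, and a gene-level count keeps reads of exons that are not deleted. The authors' deposited table, whose name gives the contrast as cKO against control, lists Foxp1 at a log2 fold change of -0.60 with a DESeq2 adjusted p of 6.02e-11. Groups are therefore named as "labelled" throughout, and each direction given here rests on labels that the targeted gene contradicts.

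The sex-linked genes also departed from the labels. Xist, which is transcribed from the inactive X chromosome, had 17599 counts in the library labelled control 1, 15165 in the library labelled cKO 1 and 14143 in the library labelled cKO 2, and 13 or fewer in the other 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty showed the reverse, for example 802, 871 and 899 counts of Ddx3y in the libraries labelled control 2, control 3 and cKO 3, and 0 in the remaining libraries. The pattern matched the labelled sex in 4 of the 6 libraries. The library labelled control 2 has a female label and a male pattern, and the library labelled cKO 2 has a male label and a female pattern.

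**Figure D1:**
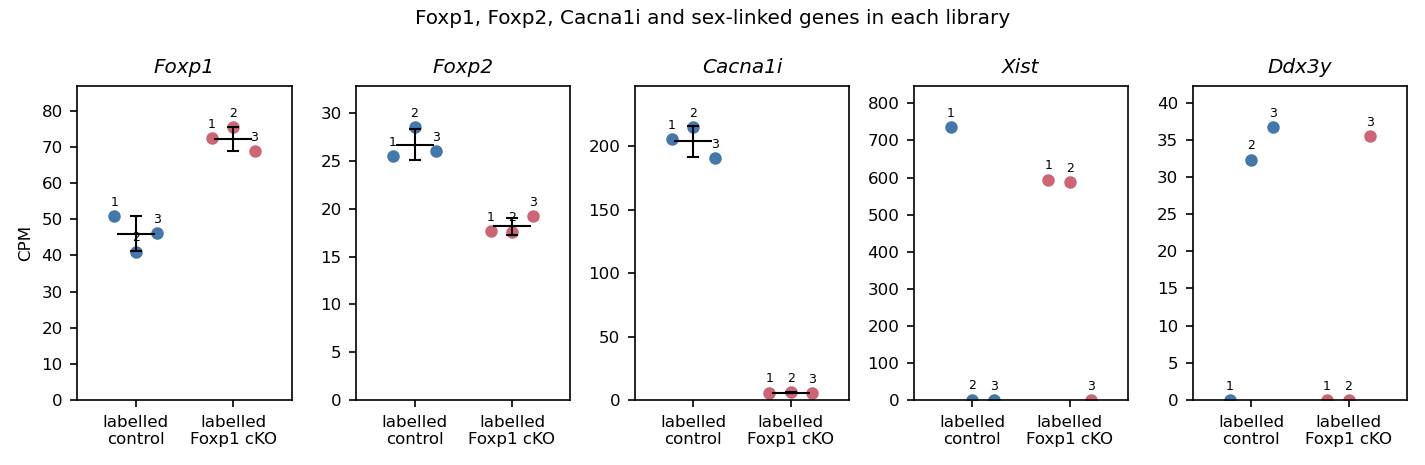
CPM values (linear axes from 0) of Foxp1, Foxp2, Cacna1i, Xist and Ddx3y in each of the 6 libraries, by labelled group, with the replicate number beside each point and bars for the mean and SD of the 3 libraries where a group is summarised. Foxp1 lay between 68.8 and 75.5 CPM in the libraries labelled cKO and between 41.1 and 50.8 CPM in those labelled control, and Cacna1i lay near 5.87 CPM against 204 CPM.

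Between the labelled genotypes, 135 genes passed an edgeR adjusted p of 0.05, of which 51 were higher and 84 lower in the libraries labelled cKO. The largest difference was in Cacna1i, the pore-forming subunit of a T-type calcium channel (ENSMUSG00000022416, chromosome 15, 80287238 to 80398279, plus strand, mm10). It fell from 204 ± 12.3 CPM (SD, n = 3) in the libraries labelled control to 5.87 ± 0.36 CPM (SD, n = 3) in those labelled cKO, a 34.8-fold difference (log2 fold change -5.12, standard error 0.07, adjusted p 4.94e-25). Gpc3, a cell-surface heparan sulphate proteoglycan (ENSMUSG00000055653, chromosome X, 52272426 to 52613950, minus strand), was at 47.7 ± 2.26 CPM (SD, n = 3) against 87.6 ± 1.55 CPM (SD, n = 3), a log2 fold change of -0.88 (adjusted p 5.32e-11). Foxp2, the paralogue of Foxp1 (ENSMUSG00000029563, chromosome 6, 14901349 to 15441977, plus strand), was at 18.2 ± 0.92 CPM (SD, n = 3) against 26.7 ± 1.63 CPM (SD, n = 3), a log2 fold change of -0.56 (adjusted p 6.31e-04). Most of the other differences were small, and 10 of the 135 genes reached 1.5-fold. The authors' deposited table gives these genes the opposite sign for cKO against control, with log2 fold changes of 5.14 for Cacna1i, 0.89 for Gpc3 and 0.52 for Foxp2.

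Lower in the libraries labelled cKO were also Eda2r, a receptor of the tumour necrosis factor family that p53 induces (log2 fold change -1.77), and C1ql4, a secreted C1q-like protein (-0.99). The adaptor Dok3 (-0.84), the cholesterol transporter Abca1 (-0.72), the imprinted gene Magel2 (-0.51), the matrix proteoglycan Vcan (-0.45) and Hif3a (-0.44) followed. Higher in the libraries labelled cKO were the complement inhibitor Cd59a (0.92), Efcab7 (0.78), the autophagy gene Vmp1 (0.40), B230118H07Rik (0.37), Cmss1 (0.37), Mrps24, a protein of the mitochondrial ribosome (0.31), Atoh7 (0.30), the ribosomal protein gene Rps14 (0.29), Selenok (0.29) and the histone gene H2bc8 (0.27). Rps14 and H2bc8 belong to families with near-identical copies, so their counts are uncertain. Foxp4 (log2 fold change -0.04, edgeR adjusted p 0.893) and Jarid2, which the series title names as a repressor of Foxp1 (-0.07, edgeR adjusted p 0.488), did not pass. All 28 genes named by the fixed rule that passed had the opposite sign in the authors' deposited table.

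**Figure D2:**
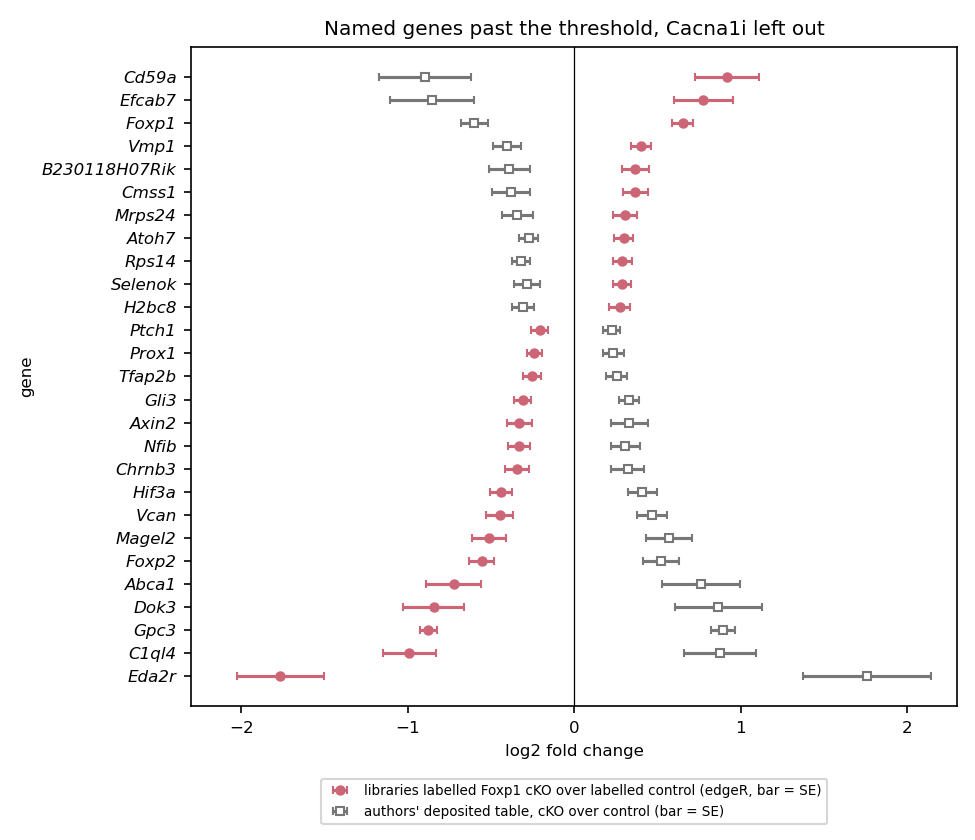
Log2 fold changes (horizontal axis) with standard errors of the named genes past an edgeR adjusted p of 0.05 (vertical axis, Cacna1i left out), for the libraries labelled Foxp1 cKO over those labelled control (filled circles) and, from the authors' deposited table, for cKO over control (open squares). The 27 genes drawn lie on opposite sides of 0, for example Foxp1 at 0.65 and -0.60.

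The count of 135 depended on single libraries: it was 34, 21 and 778 without the library labelled control 1, 2 and 3, and 361, 19 and 27 without the library labelled cKO 1, 2 and 3. It was 9 without the 2 libraries whose sex genes go against the label, called the 2 doubted libraries below. That fit has fewer libraries per group, so a call lost in it can come from lower power and need not come from the labels. An exchange of whole groups would put every label in doubt, not those 2 alone. Of the 28 named genes, 9 passed with each library left out in turn (C1ql4, Cacna1i, Eda2r, Foxp1, Foxp2, Gli3, Gpc3, Hif3a and Vmp1), and Cacna1i, Foxp1 and Gpc3 passed without those 2 libraries.

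The fold changes varied with the summed exon length of the gene. Across tested genes, which are not independent replicates, the Spearman correlation of log2 fold change with exon length was -0.27. The median exon length was 2015 bases for the 51 genes higher in the libraries labelled cKO, 10018 bases for the 84 genes lower there, and 3922 bases for all tested genes. Of the 84 lower genes, 51 lay in the decile of longest genes. With the length trend of each library removed, 38 genes passed and 28 of these were among the 135. Of the 28 named genes, 15 no longer passed. For some the fold shrank, as for Ptch1 (log2 fold change -0.21, standard error 0.05, to -0.10, standard error 0.05) and Nfib (-0.33, standard error 0.07, to -0.22, standard error 0.07). For others it hardly moved and the edgeR adjusted p came to lie just above 0.05, as for Axin2 (-0.33 to -0.32, adjusted p 0.066), Chrnb3 (-0.34 to -0.32, adjusted p 0.066) and Tfap2b (-0.25 to -0.23, adjusted p 0.053), with standard errors of 0.05 to 0.07 before and after. Atoh7 went from 0.30 to 0.22 (adjusted p 0.059) and Prox1 from -0.24 to -0.19 (adjusted p 0.054).

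**Figure D3:**
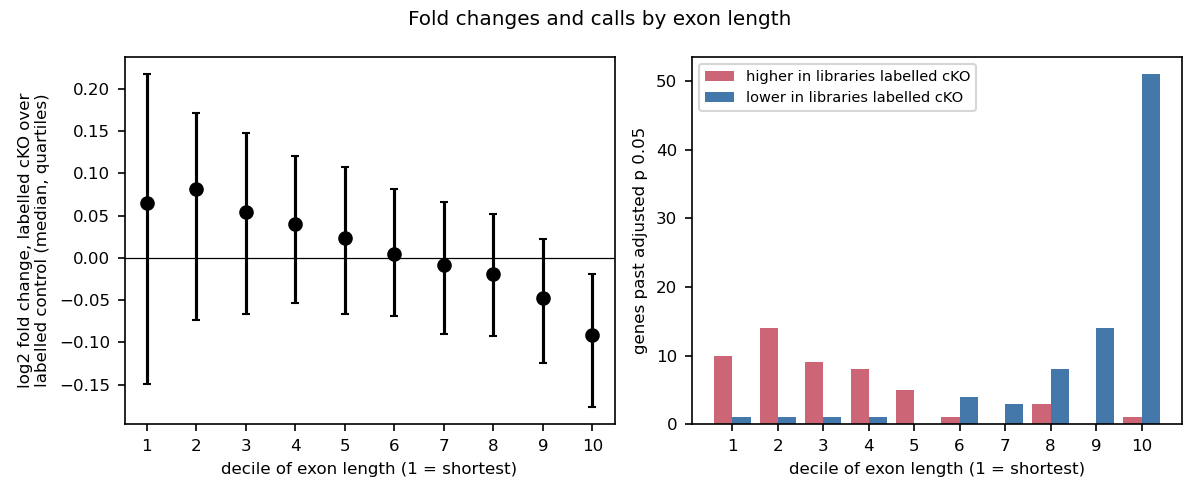
Left, median and quartiles of the log2 fold change (libraries labelled Foxp1 cKO over labelled control) in each decile of exon length, and right, the number of genes past an edgeR adjusted p of 0.05 in each decile by direction. The median went from 0.065 in the decile of shortest genes to -0.091 in the decile of longest genes, which held 51 of the genes lower in the libraries labelled cKO.

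Among the 31 gene lists fixed before the data were examined, 5 differed by camera with a preset correlation between genes of 0.01, all towards lower values in the libraries labelled cKO. None of the 5 held with an estimated correlation, with adjusted p between 0.814 and 0.89, and none by fry in a single direction, with adjusted p between 0.351 and 0.668. Of the 10 splits of the 6 libraries into 3 and 3, 9 gave 5 or more lists by camera with the preset correlation, the labelled split included. The number of lists called therefore does not set the labelled genotypes apart. Regardless of direction, 8 lists passed by fry, with adjusted p between 0.012 and 0.0448. They were the core, early-biased and late-biased progenitor, neurogenic precursor, Notch, Hedgehog, patterning, and p53 and apoptosis lists. Fry does not compare a list with other genes, so these passes do not show a change particular to those lists.

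Of the Hedgehog pathway genes, 8 of 10 were lower in the libraries labelled cKO (median log2 fold change -0.14, camera adjusted p 4.94e-04, adjusted p 0.814 with an estimated correlation). Gli3, a transcription factor of the pathway, was at 128 ± 1.23 CPM (SD, n = 3) against 158 ± 8.46 CPM (SD, n = 3), a log2 fold change of -0.31 (edgeR adjusted p 0.0033). Ptch1, the Hedgehog receptor and a target of the pathway, had a log2 fold change of -0.21 (edgeR adjusted p 0.049). Adjusted over the list alone, Gli1, Gli3 and Ptch1 were among the genes that passed. The camera call held with each library left out and without the 2 doubted libraries. The Ptch1 call was lost without the library labelled control 1 (edgeR adjusted p 0.16), control 2 (0.13), cKO 2 (0.34) or cKO 3 (0.17). Its log2 fold change was then -0.185, -0.234, -0.209 and -0.194. In the authors' deposited table Gli1, Gli3 and Ptch1 are higher in the cKO.

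The amacrine cell list was lower in the libraries labelled cKO for 11 of 17 tested genes (median log2 fold change -0.05, camera adjusted p 0.042, adjusted p 0.814 with an estimated correlation). Tfap2b, a transcription factor of amacrine cells, passed over all genes with 179 ± 1.08 CPM (SD, n = 3) against 213 ± 15.5 CPM (SD, n = 3), and a log2 fold change of -0.25 (edgeR adjusted p 0.033). The Tfap2b call was lost without the library labelled control 1 (edgeR adjusted p 0.076), control 2 (0.17), cKO 2 (0.27) or cKO 3 (0.12). Its log2 fold change was then -0.244, -0.202, -0.248 and -0.254. Adjusted over the list alone, Tfap2a, Tfap2b and Tfap2c were among the genes that passed. The call of this list was lost without the library labelled control 2 (camera adjusted p 0.154), control 3 (0.159), cKO 1 (0.124) or cKO 2 (0.1). It was also lost without the 2 doubted libraries (0.223), with the exchanged sexes as a covariate (0.197), with upper quartile normalization (0.056) and with a filter at 1 CPM (0.059). Its median was -0.03 without the library labelled control 2 and -0.08 without cKO 3.

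The p53 and apoptosis list was lower for 12 of 16 genes (median log2 fold change -0.04, camera adjusted p 0.040, adjusted p 0.814 with an estimated correlation), and Eda2r alone passed, both over all genes and adjusted over the list alone. Eda2r was at 0.78 ± 0.20 CPM (SD, n = 3) against 2.69 ± 0.38 CPM (SD, n = 3). The list was not called without the library labelled control 3 (camera adjusted p 0.295), without the 2 doubted libraries (0.068), with limma-voom (0.052) or with the exchanged sexes as a covariate (0.17). It was also not called with chromosomes X and Y left out (0.193), which removes Eda2r. Its median was -0.11, -0.08 and -0.01 without the library labelled control 1, 2 and 3, and -0.08 and -0.06 without cKO 1 and 2. The mitochondrial genome was lower for 11 of 13 genes (median log2 fold change -0.15, camera adjusted p 0.040, adjusted p 0.89 with an estimated correlation). None of its genes passed over all genes, and 4 passed adjusted over the list alone (mt-Nd1, mt-Nd4, mt-Nd5 and mt-Cytb). Mitochondrially encoded genes took 0.36% to 0.44% of the counts of each library. This call was lost without the library labelled control 1 (camera adjusted p 0.112), control 2 (0.184) or cKO 1 (0.124), without the 2 doubted libraries (0.186) and with labelled sex as a covariate (0.12). Its median was -0.08 without the library labelled cKO 1 and -0.24 without control 3.

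Lens genes were lower in the libraries labelled cKO for 16 of 16 tested genes (median log2 fold change -1.84, camera adjusted p 0.0029, adjusted p 0.89 with an estimated correlation), and none passed singly. The estimated correlation between these genes was 0.97. The lens crystallin Cryaa was at 25.5, 105 and 380 CPM in the libraries labelled control 1, 2 and 3 and at 21.6, 7.19 and 102 CPM in the libraries labelled cKO 1, 2 and 3, so the groups overlapped. Without the library labelled control 3 the list had a median log2 fold change of -0.42 and a camera adjusted p of 0.445, and without the library labelled cKO 3 the median was -3.43. The call was also lost with the exchanged sexes as a covariate (median -0.96, camera adjusted p 0.147) and without the 2 doubted libraries (0.068).

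**Figure D4:**
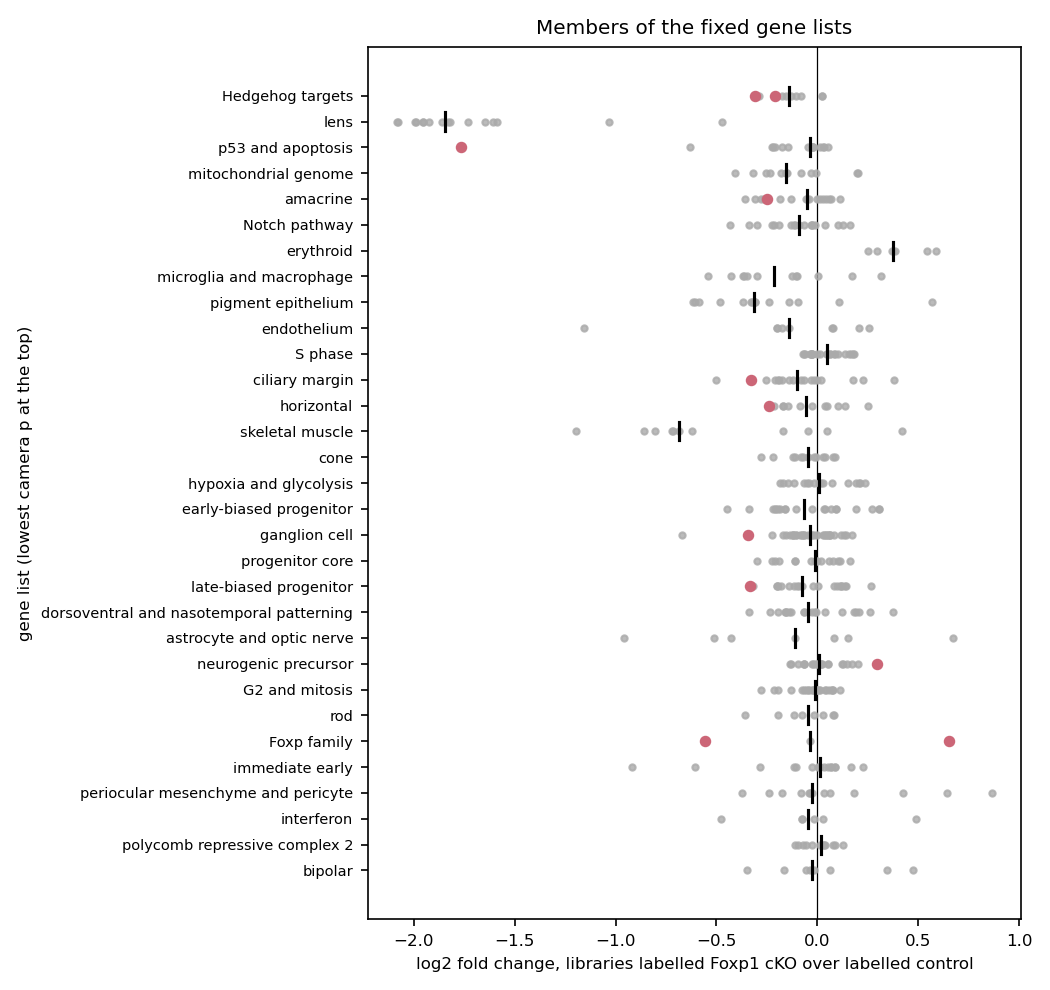
Log2 fold changes (horizontal axis, libraries labelled Foxp1 cKO over labelled control) of the tested members of each fixed gene list (vertical axis, ordered by camera p), with coloured points for genes past an edgeR adjusted p of 0.05 over all genes, grey points for the others and a black tick for the list's median. Lens genes have a median of -1.84 with no coloured point, and most retinal lists have medians near 0.

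Among retinal progenitor genes no list differed by camera. The core, early-biased and late-biased lists passed by fry regardless of direction (adjusted p 0.0448, 0.012 and 0.0131), which involves no comparison with other genes. The core progenitor list had 6 genes higher and 10 lower in the libraries labelled cKO (camera adjusted p 0.424). None passed over all genes, and 4 passed adjusted over the list alone (Six3, Hes1, Prtg and Sox9). The progenitor cyclin Ccnd1 was at 4467 ± 58.3 CPM against 4504 ± 110 CPM (SD, n = 3 each). The early-biased list had 9 higher and 11 lower (camera adjusted p 0.384), with 5 past the threshold adjusted over the list alone (Fgf3, Hmga2, Pou2f1, Foxd1 and Nr2f2). The late-biased list had 9 higher and 12 lower (camera adjusted p 0.424). In it Nfib, a transcription factor of late progenitors, was at 42.3 ± 2.84 CPM (SD, n = 3) against 53.2 ± 4.39 CPM (SD, n = 3), a log2 fold change of -0.33 (edgeR adjusted p 0.029), and 2 genes passed adjusted over the list alone, Nfib and Id3. The Nfib call was lost without the library labelled control 2 (edgeR adjusted p 0.144), cKO 2 (0.101) or cKO 3 (0.102). Its log2 fold change was then -0.26, -0.36 and -0.35. The authors' deposited table has Nfib, Casz1 and Zfp36l1 of this list higher in the cKO.

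The neurogenic precursor list had 12 genes higher and 10 lower in the libraries labelled cKO (camera adjusted p 0.537). Atoh7, the proneural factor needed for retinal ganglion cells (ENSMUSG00000036816, chromosome 10, 63099651 to 63101279, plus strand), was at 533 ± 25.4 CPM (SD, n = 3) against 434 ± 26.3 CPM (SD, n = 3), a log2 fold change of 0.30 (edgeR adjusted p 0.018). It was the 1 gene of the list that passed, both over all genes and adjusted over the list alone, and its call was lost without the library labelled control 2 (edgeR adjusted p 0.144) or cKO 2 (0.229). The log2 fold change of Atoh7 was then 0.25 and 0.27. The authors' deposited table has Atoh7 at -0.27 (DESeq2 adjusted p 4.54e-04) for cKO against control, and Hes6 lower in the cKO as well.

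Of the lists of differentiating neurons, ganglion cell genes were higher for 14 and lower for 20 in the libraries labelled cKO (camera adjusted p 0.409), with the nicotinic receptor subunit gene Chrnb3 at -0.34 (edgeR adjusted p 0.033). Horizontal cell genes were higher for 5 and lower for 7 (camera adjusted p 0.303), with Prox1 at -0.24 (edgeR adjusted p 0.017). Both genes also passed adjusted over the list alone. Cone genes were higher for 4 and lower for 9 (camera adjusted p 0.324), with Otx2 at 0.03 and Prdm1 at -0.05, and Rbp3 passed adjusted over the list alone. Rod genes (3 higher, 5 lower, camera adjusted p 0.696) and bipolar genes (3 higher, 5 lower, camera adjusted p 0.982) had no gene past the threshold over all genes or adjusted over the list alone. Pdc and Rom1 of the rod list were at -0.08 and 0.03, and Irx5 and Lhx4 of the bipolar list at -0.02 and -0.04. Ciliary margin genes were higher for 4 and lower for 14 (camera adjusted p 0.279). In that list Axin2, a target of Wnt signalling, had a log2 fold change of -0.33 (edgeR adjusted p 0.040), and Gas1, Axin2 and Col9a1 passed adjusted over the list alone.

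S phase genes were higher for 14 of 24 in the libraries labelled cKO (camera adjusted p 0.22) and G2 and mitosis genes for 9 of 24 (camera adjusted p 0.628). None passed over all genes or adjusted over the list alone in either. Notch pathway genes were lower for 15 of 19 (median log2 fold change -0.09, camera adjusted p 0.055), with Notch1 at -0.30 (edgeR adjusted p 0.194) and none past the threshold adjusted over the list alone. This list passed in several other fits, for example with the exon length trend removed (camera adjusted p 0.0085), without the 2 doubted libraries (0.0058), with labelled sex as a covariate (0.015) and with limma-voom (0.039), but not with an estimated correlation (adjusted p 0.814). With 1 library left out, the camera adjusted p lay between 0.014 (without the library labelled control 2) and 0.18 (without cKO 3). Patterning genes were lower for 14 of 21 (camera adjusted p 0.509), and 7 passed adjusted over the list alone, 3 higher and 4 lower (Vax2, Ephb3, Efnb1, Cyp26a1, Foxd1, Epha6 and Crabp1). Genes of polycomb repressive complex 2, with which Jarid2 associates, were higher for 7 of 12 (camera adjusted p 0.975). Ezh2 was at 0.08 and Rbbp4 at 0.13, and none passed. Immediate early genes (11 of 17 higher, camera adjusted p 0.933) and interferon genes (2 of 6 higher, camera adjusted p 0.975) had none past either threshold. Hypoxia and glycolysis genes were higher for 9 of 17 (camera adjusted p 0.384), with Pgk1, Ldha and Pdk1 past the threshold adjusted over the list alone. The 3 tested members of the Foxp family had no shared direction (camera adjusted p 0.711). Foxp1 was higher and Foxp2 lower, both also past the threshold adjusted over the list alone, and Foxp4 did not pass (log2 fold change -0.04).

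Markers of other tissues in or near the eye did not pass by camera in the main comparison apart from the lens, and several passed in other fits. In none of these lists did a gene pass over all genes in the main comparison. The authors' deposited table has Col1a1 and Col1a2 lower (DESeq2 adjusted p 3.53e-06 and 1.25e-07) and Kdr higher (0.026) in the cKO. Pigment epithelium genes were lower for 13 of 15 in the libraries labelled cKO (camera adjusted p 0.192), and passed with limma-voom (0.039) and without the library labelled cKO 1 (4e-08), where the median log2 fold change moved from -0.31 to -0.94. It did not pass with an estimated correlation in the main comparison (adjusted p 0.89). Pmel was at 33.3 ± 22.7 CPM against 46.7 ± 11.8 CPM (SD, n = 3 each), and Stra6 and Trpm1 had log2 fold changes of -0.14 and -0.33. Microglia and macrophage genes were lower for 9 of 12 (camera adjusted p 0.192, and 0.031 with the exon length trend removed, but adjusted p 0.814 with an estimated correlation in the main comparison), with Csf1r at -0.35 and Cx3cr1 at -0.30. Erythroid genes were higher for 6 of 6 (camera adjusted p 0.072), with Hbb-bs at 0.54, Hba-a1 at 0.37 and Hba-a2 at 0.30, the last 2 being near-identical copies. The erythroid list passed with no filter (0.0036), without robust estimation (0.024), with limma-voom (0.026) and without the library labelled control 3 (2.11e-04) or cKO 3 (0.0047), with a median log2 fold change of 0.38 in the main comparison, 0.71 without control 3 and 0.61 without cKO 3. It did not pass with an estimated correlation (adjusted p 0.89) or by fry (adjusted p 0.668) in the main comparison. Endothelial genes were higher for 4 and lower for 5 (camera adjusted p 0.202), and Kdr passed adjusted over the list alone with a log2 fold change of -0.17. Cldn5 and Egfl7 were at -0.20 and -0.14. Periocular mesenchyme and pericyte genes were higher for 6 and lower for 7 (camera adjusted p 0.975, and 0.0498 without the 2 doubted libraries, but adjusted p 0.982 with an estimated correlation in the main comparison), with Col1a1 at 0.86, Col1a2 at 0.64 and Col6a1 at -0.08. Astrocyte and optic nerve genes were higher for 3 and lower for 4 (camera adjusted p 0.509), with Pax2 at -0.51, Pdgfra at -0.43 and Aldh1l1 at 0.15. Skeletal muscle genes were lower for 9 of 11 (camera adjusted p 0.32, and 0.0036 or 0.014 without the library labelled control 1 or 2, but adjusted p 0.89 with an estimated correlation in the main comparison), with Ttn at -0.81, Myh3 at -0.72 and Acta1 at -0.72.

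The authors' deposited table holds 21080 genes, of which 7593 have an adjusted p, and 681 of these are under 0.05, 455 higher and 226 lower in the cKO. Of the 135 genes called from the counts, 135 have the opposite sign in the authors' deposited table. An adjusted p is given there for 124 of them and is under 0.05 for 122. In the other direction, 680 genes called in the authors' deposited table were tested from the counts, and 680 had the opposite sign. Across the 17275 genes in both, the Spearman correlation of the log2 fold changes was -0.95. Read with the contrast that the authors' deposited table names, Cacna1i, Gpc3, Gli3, Ptch1, Nfib, Tfap2b and Prox1 are higher and Foxp1, Atoh7, Vmp1, Rps14, Col1a1 and Col1a2 lower in the cKO.

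A test of whether the labelled genotype effect differs between the labelled sexes called 15 genes by edgeR. Of the 17275 tested genes, 633 had an unadjusted p under 0.05, a smaller share than the 0.05 that chance alone would give. The histone genes Hist1h2an and Hist1h2br had the smallest p with Hba-a2, and their families hold near-identical copies. The 15 genes included 5 of muscle (Acta1, Myh3, Ttn, Myl4 and Myl1), 2 of haemoglobin (Hba-a1 and Hba-a2) and the imprinted genes Igf2, Dlk1 and H19. The fit had 2 residual degrees of freedom, 1 library labelled as a male control and 1 labelled as a female cKO, and the sex label went against the sex-linked genes in 2 libraries.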

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

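The tests in this part were chosen after the values were seen, apart from the counts over other splits of the libraries and the interaction test.

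An edgeR test of whether the labelled genotype effect differs between the labelled sexes passed for 15 genes, which is why it is listed here, but 2 of its arms hold 1 library each and a single library can give such calls. Acta1, the actin of skeletal muscle, was at 11.3 CPM in the library labelled control 3, the single labelled male control, and between 1.55 and 3.72 CPM in the other 5. The fit has 2 residual degrees of freedom, and the sex labels are in doubt, so no difference between the sexes is drawn from it.

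Foxp1 and the sex-linked genes go against the labels, with Foxp1 at 72.2 ± 3.36 CPM in the 3 libraries labelled cKO and at 46.0 ± 4.85 CPM (SD, n = 3) in the 3 labelled control. A single wrong label or 1 exchanged pair of libraries is argued against, since all 3 libraries labelled cKO have more Foxp1 than every library labelled control. Right genotype and sex labels with more Foxp1 transcript in the cKO are argued against too, since the sex-linked genes match the labelled sex in 4 of 6 libraries. What stays open is that the 2 groups may be exchanged as wholes in the labels: with the labelled sexes exchanged number for number, 6 of 6 libraries match. That exchange alters the sex label of the libraries labelled control 2 and cKO 2 alone. So this match cannot tell exchanged groups from wrong sex labels in those 2 libraries. A DESeq2 fit with these exchanged sexes and the contrast of labelled control over labelled cKO gave log2 fold changes within 0.0097 of the authors' deposited table and 681 calls, as there, against 490 calls with genotype alone, 264 with the labelled sexes and 508 with the replicate number. These fits used the 21080 genes of the authors' deposited table. The fit with the exchanged sexes shows that this table and the labels of the counts name the groups in opposite ways. Foxp1 is lower in the group that this table names cKO. Wrong sex labels in those 2 libraries alone would account neither for this opposite naming nor for the direction of Foxp1.

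Cacna1i and Gm28528 differed far more than any other gene past the threshold. Gm28528, annotated as antisense (ENSMUSG00000099635, chromosome 17, 85619326 to 85621001, minus strand, mm10), lies within the span of Six3 and was at 3.28 ± 0.41 CPM (SD, n = 3) in the libraries labelled cKO and 59.9 ± 5.85 CPM (SD, n = 3) in those labelled control (18.3-fold). A copy change of 2-fold or more across the surrounding region is argued against, since 0 of the neighbours within 500 kb at 1 CPM or more were lower by 2-fold, and the 13 neighbours of Cacna1i ranged from -0.25 to 0.47 in log2 fold change. The 10 neighbours of Gm28528 ranged from -0.58 (Gm27427) to 0.25 (Six2), and the lowest overlap the span of Six3. A smaller copy change, or one confined to the span of Six3, is therefore not excluded. Reads from a Cre construct that carries part of Six3 stay open for Gm28528 only: Six3os1 had a log2 fold change of -0.376 (edgeR adjusted p 0.0010), while Six3 itself did not pass over all genes (-0.19, edgeR adjusted p 0.143) and passed adjusted over the progenitor list alone. The authors' deposited table has Six3 at 0.24 for cKO against control with a DESeq2 adjusted p of 0.0013. The sequence and insertion site of the construct are not given in the sources used here. If such reads are the source, they would place the construct in the libraries labelled control. A biological change of Cacna1i after loss of Foxp1 was not tested apart from the genotype comparison itself, which cannot part it from an effect of the construct, since every cKO animal carries Cre and no control does.

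Short genes were called higher and long genes lower in the libraries labelled cKO. A length trend that differs between libraries is a candidate explanation: the Spearman correlation of a library's deviations with exon length was 0.20, 0.17 and 0.02 in the libraries labelled control 1, 2 and 3 and -0.06, -0.20 and -0.25 in those labelled cKO 1, 2 and 3. These values follow the labelled groups, so such a trend cannot be told apart from a genotype effect that varies with exon length. Removing it left 38 genes, but removal takes out either, so this drop does not decide between them. Foxp1 (0.75), Cacna1i (-5.05), Gpc3 (-0.92) and Foxp2 (-0.44) still passed with the trend removed. A change of ribosomal protein genes beyond the length trend stays open: with the trend removed, 78 of 79 were still higher, with a median log2 fold change of 0.11, and 3 passed over all genes by edgeR. Fry, which does not compare them with other genes, gave p = 0.035, and camera with an estimated correlation, which does, gave p = 0.131.

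Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the labelled genotypes, which is the labelled split itself, with 135 genes against at most 20 in any other. For gene lists, 9 of the 10 splits, the labelled split included, gave 5 or more, and the highest other gave 10. The number of lists called by camera with the preset correlation therefore does not set the labelled genotypes apart from other splits. For the number of genes, a share under 0.05 cannot be reached with 10 splits.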

How the results depend on the processing

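Added after seeing the data were the exchanged-sex covariate, the removal of the exon length trend and the fits without the 2 libraries whose sex-linked genes go against the label. The exchanged sexes match the sex-linked genes in every library, so that covariate adjusts for the observed sex. The main fit has no sex term. Higher Foxp1 in the libraries labelled cKO held in every fit run, with a log2 fold change between 0.54 and 0.75. The 135 genes became 742 with no filter on low counts, 83 with at least 1 CPM in 3 libraries, 10 without robust estimation, 473 with DESeq2, 13 with limma-voom and 10 at 1.5-fold or more. They became 746 with the exchanged sexes as a covariate, 690 with DESeq2 and the exchanged sexes (both DESeq2 counts are over all genes with a count, not the genes of the authors' deposited table alone), 38 with the length trend removed and 9 without the 2 libraries (4 shared). Leaving out 1 library gave 19 (without the library labelled cKO 2) to 778 (without control 3) genes. The 5 gene lists became 0 by fry, 0 with an estimated correlation, 3 with the exchanged sexes, 3 without the 2 libraries, 7 each with no filter, without robust estimation, with limma-voom and with the length trend removed, and 3 (without the library labelled control 3) to 6 (without cKO 3) with 1 library left out. The interaction count of 15 became 8 with at least 1 CPM in 3 libraries and 8 with DESeq2, and it was not refitted with libraries left out. The authors' deposited table has 232 genes at an adjusted p under 0.01, against 681. The cause of these shifts was not tested.

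With the replicate number as a replicate block, 1065 genes and 3 lists were called. The numbers do not pair the libraries: correlations of same-numbered deviations were 0.09, -0.05 and 0.20, not every library correlated best with its own number, and the labels give 1 litter.

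RLE gave 126 genes, upper quartile 93, labelled sex as a covariate 113, and 114 without chromosomes X and Y. Of the 28 named genes called, 3 (Foxp1, Cacna1i and Gpc3) passed in every fit that tested them and 0 changed sign. Calls were lost for 20 without robust estimation, 20 with limma-voom, 15 with the length trend removed and 25 without the 2 libraries. Values not called in either fit were compared for the call only. Depth limits the low genes: Eda2r rests on 0.78 CPM in the libraries labelled cKO.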

Other observations

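The gene groups in this part were chosen, and tested, after their values were seen. Ribosomal protein genes, which encode the cytoplasmic ribosome, were higher in the libraries labelled cKO for 79 of 79 tested genes, with log2 fold changes between 0.05 and 0.29 and a median of 0.17, and 10 passed over all genes by edgeR. Camera with an estimated correlation of 0.71 gave p = 0.101, and fry gave p = 0.027. Nuclear genes of the respiratory chain were higher for 75 of 78, with a median of 0.14, 2 of which passed. Camera with an estimated correlation gave p = 0.113 and fry p = 0.043. With the exon length trend removed, 68 of 78 were higher, the median was 0.08 and none passed over all genes by edgeR. Camera with an estimated correlation then gave p = 0.166 and fry p = 0.074. These genes are short, with median exon lengths of 1781 and 1696.5 bases. Per library, the mean log2 deviation of ribosomal protein genes was -0.17, -0.06 and -0.03 in the libraries labelled control 1, 2 and 3, and 0.03, 0.14 and 0.09 in those labelled cKO 1, 2 and 3. Near-identical processed copies of ribosomal protein genes make single counts uncertain.

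Lens transcripts varied more between libraries than between the labelled groups. The mean log2 deviation of the lens genes was -1.04, 0.91 and 2.63 in the libraries labelled control 1, 2 and 3, and -0.93, -2.45 and 0.88 in those labelled cKO 1, 2 and 3. Cryaa had 9024 counts in the library labelled control 3 and 173 in the library labelled cKO 2. Muscle transcripts were also highest in the library labelled control 3, with Ttn at 41.9 CPM against 13.2 to 24.9 CPM elsewhere.

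The first principal component, with 32.2% of the variance, separated the 3 libraries with high Xist (-10.8, -18.3 and -25.5) from the 3 with Y-linked counts (15.5, 21.8 and 17.3), and not the labelled genotypes. The same 3 libraries with high Xist also had low lens deviations (-1.04, -0.93 and -2.45), against 0.91, 2.63 and 0.88 in the others. This component therefore cannot part sex from lens content. Of all tested genes, 20.1% had no overlap between the labelled groups, where chance gives 10%.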
